A study of Mus musculus with 8 samples.

How the data were processed

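Splenic cells from wild-type male C57Bl/6j mice, 8 weeks old, were profiled on 8 Affymetrix mouse Gene ST 1.0 arrays, 4 of hemophagocytes and 4 of resting macrophages. Per the labels' protocols, mice received 4 intraperitoneal doses, given on alternate days. The dose was either 37.5 ug of CpG1826, an oligonucleotide that stimulates Toll-like receptor 9, together with 200 ug of the blocking antibody 1B1.3A against the IL-10 receptor, or 200 uL of PBS alone. Touch preparations of the spleen were laser-dissected at 20 target cells per mouse, and the captured cells were pooled, per the labels' protocols. How the target cells were recognised is not given in the sources used here. RNA was amplified with the WT-Ovation One-Direct system and labelled with the Encore Biotin module, per the labels' protocols. Amplification from so few cells can leave out or overstate individual transcripts, and its extent cannot be read from the values.

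The deposited values are on the log2 scale, 1 value per probe set and array, as judged from their range. Affymetrix Expression Console 1.1 is named in the submitters' processing notes. The background correction, the summary over probes and the normalization between arrays are not given in the sources used here. The arrays' medians lay between 6.10 and 6.17, and the deposited values were used without further scaling. For arrays there is no read depth, and the 4 arrays per group limit the precision.

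The table held 35556 probe sets. The platform annotation gave 1 gene symbol for 21789 of them, several for 1621, and did not list 12146. Probe sets with several genes or none were left out of all gene results, so the adult globins, Gapdh, H2-K1 and H2-D1, among others, were not tested here. Entrez identifiers of 21698 single-gene probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only and altered 0 symbols. The array's genome build is not given in the sources used here and no coordinates are printed. Where a gene had several single-gene probe sets (999 genes), the probe set with the highest mean over all 8 arrays stood for it, which left 19938 genes. No filter on dim probe sets was applied.

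The groups and the replicate numbers (2, 3, 5 and 6 for hemophagocytes; 3, 4, 5 and 6 for resting macrophages) were taken from the sample titles. The labels do not say which mice stand behind each array or whether a pool holds cells of 1 mouse, so p-values measure the spread between these samples, which may be partly technical. Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All changes are hemophagocyte minus resting macrophage, with positive values higher in hemophagocytes. Before the data were examined, 37 gene lists were fixed, 24 of cell programs and 13 of cell type markers. All 37 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares the members with all other genes. Members were also adjusted over the list alone. Exact permutation of the 8 arrays between the groups cannot give a two-sided p below 0.0286.

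The genes named in the text follow a rule set at the same time. In each direction it takes the 10 genes with the largest change among those past the threshold whose groups did not overlap, filled up with the genes of smallest unadjusted p, which are then given as values that did not pass; predicted genes, pseudogenes, microRNAs, and olfactory and vomeronasal receptors were passed over. From each list it takes up to 4 members, those of smallest p where none passed.

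The alternatives set beforehand were quantile, median and cyclic loess normalization, a filter on genes below the median level, an intensity trend with a robust prior, array weights, the mean of all probe sets of a gene, each array left out in turn, the replicate number as a block, camera with an estimated correlation, and fry. Alternatives added after seeing the data were a covariate for array background (the mean of 1194 olfactory and vomeronasal receptor genes), leaving out hemophagocytes 3 and 5, leaving out hemophagocyte 2 with resting macrophage 3, and an exact permutation test of array means per list. The other pairs of hemophagocytes were left out as well, for their counts of lists and genes only. The scripts were tested on simulated data before use. For this comparison, 20 draws of 19938 genes with normal noise of the measured size gave back 96.2% of changes of 1 log2 unit and 99.3% of changes of 2, with 9.05 false calls per draw. A list moved by 0.3 log2 units was called in 20 of 20 draws, and some other list in 2. The simulated genes were drawn independently of each other. In the real data the estimated correlation within a list reached 0.42 for NK cells and 0.30 for the cytosolic ribosome. The simulated rates for lists therefore need not hold for the real lists. The simulated noise leaves out the large values that single real arrays hold. The simulated changes were placed on random genes, while genes with large real changes could vary far more. The SD in hemophagocytes was 2.48 for B2m and 1.70 for Cox6c, and the recovery rates need not hold for such genes. Figures were drawn with matplotlib 3.10.9.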

Results

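Hemophagocytes, macrophages that have engulfed blood cells, were captured from the spleens of mice given CpG1826 and an IL-10 receptor blocking antibody, and resting macrophages from the spleens of mice given PBS. Each group had 4 arrays. The comparison asks how the transcripts of hemophagocytes differ from those of resting splenic macrophages, and in particular whether they carry genes of alternative macrophage activation. No macrophages without engulfed cells were arrayed from the treated mice. Effects of engulfment therefore cannot be told apart from those of CpG1826 and the antibody. The arrays had medians of 6.10 to 6.17 on the log2 scale. Resting macrophage arrays resembled each other closely, with Pearson correlations across genes of 0.968 to 0.975, and hemophagocyte arrays less so, at 0.940 to 0.965. Between the groups the correlations ran from 0.929 to 0.974, and the highest of these joined hemophagocyte 2 and resting macrophage 3. Genes are not independent replicates, so these correlations carry no test. High values were concentrated on a few hemophagocyte arrays. Hemophagocytes 3 and 5 held 154 and 159 genes more than 1 log2 unit above the gene's own median over the 8 arrays, hemophagocytes 2 and 6 held 13 and 30, and each resting array held 7 to 16.

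**Figure D1:**
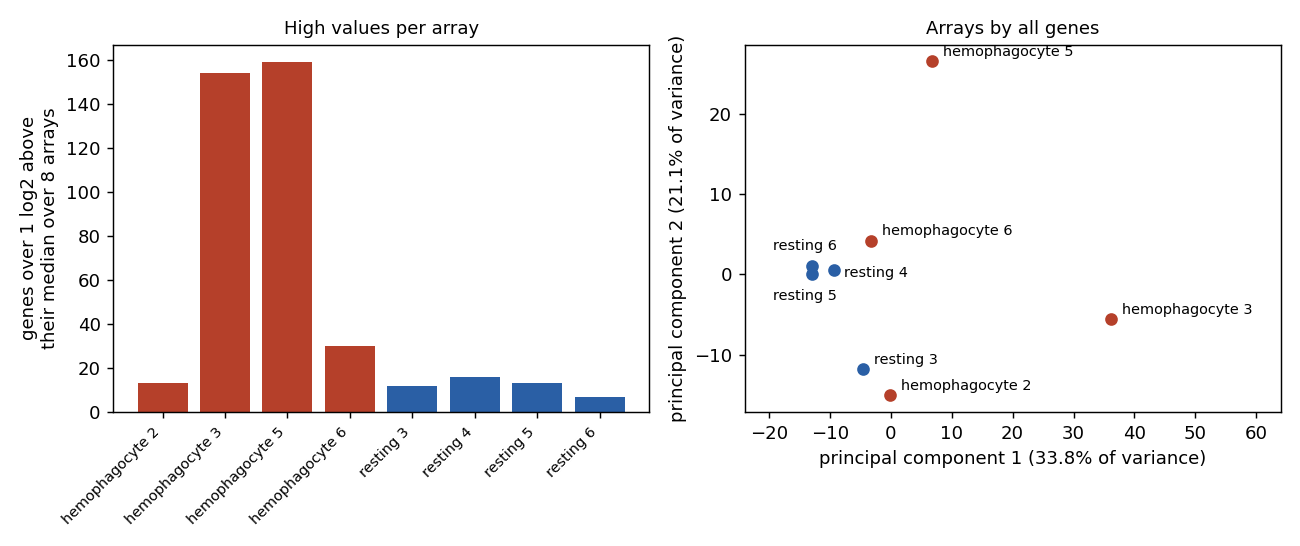
The left panel gives, for each of the 8 arrays, the number of genes more than 1 log2 unit above their own median over all arrays, and the right panel places the arrays on principal components 1 and 2 of all genes (red, hemophagocytes; blue, resting macrophages). Hemophagocytes 3 and 5 hold 154 and 159 such genes, and hemophagocyte 3 lies at 36.2 on component 1 while the other arrays lie between -12.9 and 6.8.

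Gng5 and S100a6 were higher in hemophagocytes than in resting macrophages. Gng5, which encodes a gamma subunit of heterotrimeric G proteins, rose 2.98-fold, from 6.03 ± 0.13 to 7.60 ± 0.21 (log2, mean ± SD, n = 4 each). S100a6, a calcium-binding protein of the S100 family, rose 4.05-fold, from 6.00 ± 0.36 to 8.02 ± 0.51. In both genes all 4 hemophagocyte arrays lay above all 4 resting arrays. No gene was lower past the threshold. Among 19938 genes, limma called 2 higher and 0 lower, with adjusted p = 5.2e-04 for Gng5 (probe set 10434672; log2 change 1.58, SE 0.11) and adjusted p = 0.048 for S100a6 (probe set 10493820; log2 change 2.02, SE 0.24). At an unadjusted p under 0.05 there were 306 genes higher and 1006 lower, 1312 in all where 997 are expected by chance. The excess of lower genes depended on scaling, with 488 higher and 748 lower after quantile normalization, 495 and 691 after median centring, and 611 and 549 after cyclic loess. It also depended on single arrays, with 310 and 553 without hemophagocyte 3, 201 and 724 without resting macrophage 4, and 208 and 659 without resting macrophage 5. The groups did not overlap in 739 genes, 160 of them with higher and 579 with lower values in hemophagocytes. This is 3.71% of genes, against 2.86% by chance. Over all genes the median change was -0.04, and 36.1% of genes had a change above 0. Counts of list members above or below 0 are to be read against this share. The 1194 olfactory and vomeronasal receptor genes, sensory neuron genes taken here as a measure of array background, had a median change of -0.15. Their mean was 5.99 to 6.16 on the resting arrays, near the resting means of Gng5 and S100a6. Gng5 passed in 19 of 19 alternative settings. The S100a6 call ended when any of 6 single arrays was left out, with adjusted p = 0.093 without hemophagocyte 3, 0.13 without hemophagocyte 6, and 0.15, 0.19, 0.052 and 0.23 without resting macrophage 3, 4, 5 and 6. With all arrays it ended with median centring (adjusted p = 0.061), cyclic loess (0.065) and the intensity trend and robust prior (0.66). It also ended with the replicate number as a block (adjusted p = 0.21). Hemophagocyte 2 and resting macrophage 4 add nothing to that contrast, since their numbers occur in only 1 group.

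Genes next in order were also higher on the hemophagocyte arrays but did not pass. Saa3, an acute phase serum amyloid A protein made by activated macrophages, averaged 10.74 ± 0.23 in hemophagocytes and 7.77 ± 1.05 in resting macrophages (limma adjusted p = 0.11), and reached adjusted p = 0.022 without resting macrophage 4. Ftl1, the ferritin light chain that stores iron, averaged 7.83 ± 0.94 against 5.29 ± 0.45 (adjusted p = 0.27). Snora73a, a small nucleolar RNA, had a log2 change of 0.56 with the same adjusted p of 0.27. Ndufb8, a subunit of respiratory complex I, had a change of 0.60 (adjusted p = 0.42). Rps20, a protein of the small ribosomal subunit, had the largest change of these at 4.50 (adjusted p = 0.55). Resting macrophage 3 stood at 7.86 for Rps20 and the other resting arrays at 4.18 to 4.40, and without that array adjusted p was 0.019. Apart from that value, resting Ftl1 and Rps20 lay below the mean of the olfactory and vomeronasal receptor genes on the same arrays. Tomm7, part of the protein import pore of the outer mitochondrial membrane, changed by 1.85 (adjusted p = 0.75), and adjusted p was 0.014 without hemophagocyte 3. Wnt2 (0.33) and Tesc (0.46) completed the 10, both at adjusted p = 0.75. Without hemophagocyte 2, limma called 11 genes higher, among them B2m. Without hemophagocyte 6, resting macrophage 5 or resting macrophage 6, 1 gene was called.

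Of the genes with lower values in hemophagocytes none passed, and the 10 named by p had changes of -0.29 to -0.44. Bub3, a spindle checkpoint protein, had a log2 change of -0.39 (SE 0.07, limma adjusted p = 0.55). The other 9 all had adjusted p = 0.75. Spred2, an inhibitor of Ras-ERK signalling, stood at -0.44, Zcchc13 at -0.44, Tex45 at -0.40, Pilrb2 and Iftap at -0.37, the protocadherin Pcdh1 at -0.35, the placental prolactin-family gene Prl8a9 at -0.34, Maf1, a repressor of RNA polymerase III, at -0.32, and Kansl2 at -0.29. In Spred2 and Iftap a dimmer probe set had changes of -0.10 and 0.00, so the probe sets of these genes disagreed.

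**Figure D2:**
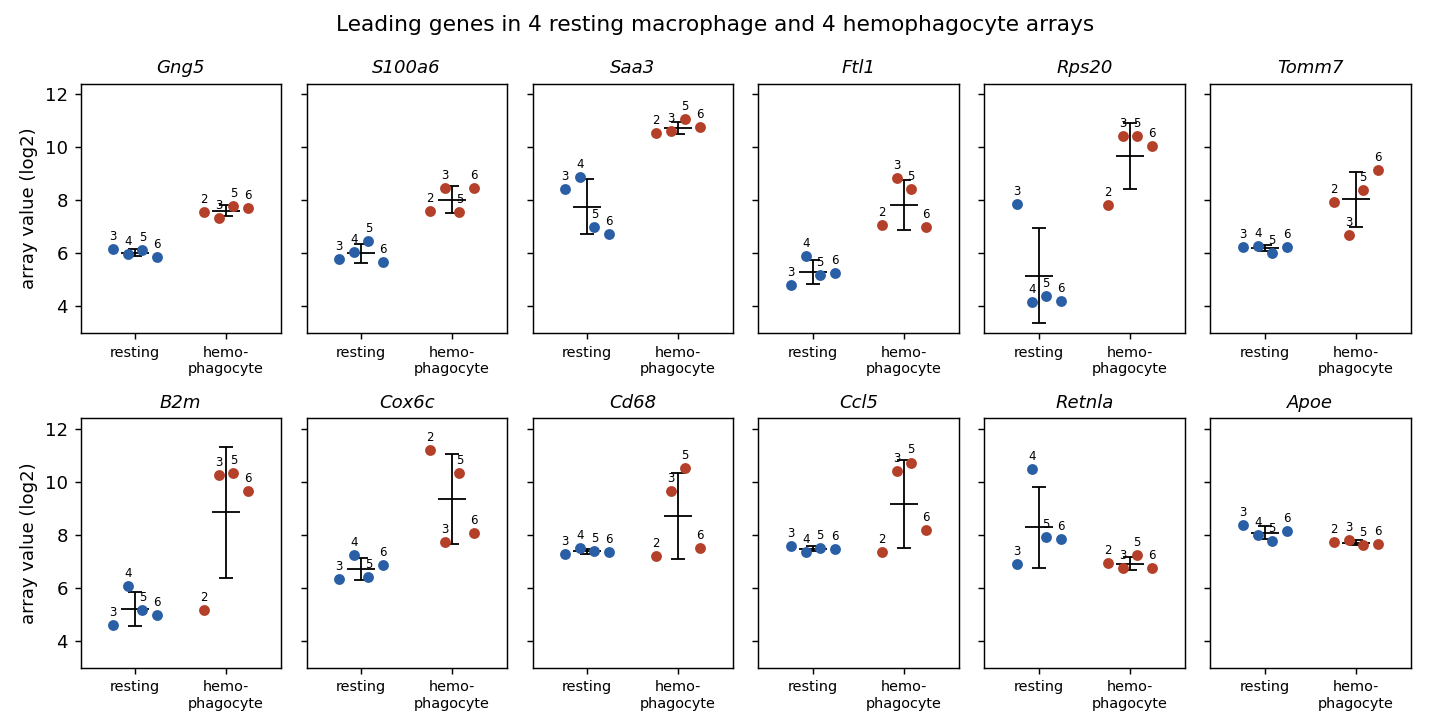
Array values (log2) of 12 genes in 4 resting macrophage arrays (blue) and 4 hemophagocyte arrays (red), each dot 1 array marked with its replicate number, with mean and SD in black. All hemophagocyte arrays lie above all resting arrays for Gng5, S100a6, Saa3, Ftl1 and Cox6c; hemophagocyte 2 stands at 5.17 for B2m while hemophagocytes 3, 5 and 6 stand at 9.67 to 10.34.

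Of the 37 gene lists, 8 were higher in hemophagocytes and 1 was lower. Genes of mitochondrial oxidative phosphorylation, cytosolic ribosomes, MHC class I antigen presentation, the lysosome, complement, the interferon gamma response, the type I interferon response, and chemokines with their receptors were higher as groups relative to other genes. Markers of natural killer (NK) cells were lower as a group. None of these calls held with an estimated correlation, where the smallest adjusted p = 0.20, and none of the 8 higher lists passed when hemophagocytes 3 and 5 were left out together, where the smallest adjusted p = 0.62. No single member of any list passed over all genes: of 529 different members, 0 passed in limma, and 37 were higher and 19 lower at an unadjusted p under 0.05.

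Oxidative phosphorylation had the smallest p among the lists (limma camera adjusted p = 2.9e-06; adjusted p = 0.20 with an estimated correlation). Its median log2 change was 0.10 and its mean 0.31, and 22 of 30 measured members had values above 0. Adjusted over the list alone, 2 members passed and 0 did over all genes. These were Ndufb8 and the cytochrome c oxidase subunit Cox6c, which averaged 9.35 ± 1.70 in hemophagocytes and 6.72 ± 0.42 in resting macrophages. Cox6a1, another cytochrome c oxidase subunit, had a change of 2.08 and Ndufa5 of complex I one of 0.54, and neither passed. The cytosolic ribosome list was called at adjusted p = 5.6e-05 (adjusted p = 0.36 with an estimated correlation), with a median change of 0.36 and 12 of 16 members above 0. None of its members (0 of 16) passed adjusted over the list alone. Rpl27 (1.09), Rpl10a (0.91), Rpl8 (0.53) and Rpl13 (0.47) had the smallest p values. All 4 probe sets of Rpl10a and of Rpl27 had changes above 0. The ribosome call ended without hemophagocyte 3, where the median change fell to 0.03 (adjusted p = 0.17), and without hemophagocyte 5 the median was 0.23.

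MHC class I presentation was higher at adjusted p = 1.1e-04 (adjusted p = 0.35 with an estimated correlation), with a median change of 0.10 and a mean of 0.51 over 11 measured members, 8 of them above 0. The median was 0.05 without resting macrophage 6. Adjusted over the list alone, 2 members passed. B2m, the invariant light chain of class I molecules, had the largest change of any named list member at 3.64 (SE 0.96), with 3 hemophagocyte arrays between 9.67 and 10.34, hemophagocyte 2 at 5.17, and resting arrays between 4.60 and 6.08. The olfactory and vomeronasal receptor genes averaged 5.95 on hemophagocyte 2 and 5.99 to 6.16 on the resting arrays. B2m lay below that mean on each of these arrays, so whether its transcript was detected on them cannot be told. Psmb8, an immunoproteasome subunit, had a change of 0.47. Psmb10 (0.38) and the endoplasmic reticulum chaperone Pdia3 (0.91) did not pass. Without hemophagocyte 2, B2m passed over all genes at adjusted p = 6.0e-04. The interferon gamma response, called at adjusted p = 0.0045 (adjusted p = 0.20 with an estimated correlation), shares its leading members with that list. Psmb8, Psmb10, Gbp7 (0.21) and Psmb9 (0.14) had the smallest p values, 10 of 17 members lay above 0, and the median change was 0.02, or 0.006 to 0.057 when single arrays were left out. This call ended when genes below the median level were left out (adjusted p = 0.066). The type I interferon response was called at adjusted p = 0.013 (adjusted p = 0.36 with an estimated correlation), with 11 of 20 members above 0. The antiviral Oasl1 stood at 0.28, the transcription factor Irf7 at 0.44 and the nucleotide kinase Cmpk2 at 0.15, while Usp18, which restrains interferon signalling, stood at -0.20. Adjusted over the list alone, 0 members of either interferon list passed. The type I call ended without hemophagocyte 5 (adjusted p = 0.54) and without resting macrophage 3 (adjusted p = 0.060).

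The lysosome list was higher at adjusted p = 1.4e-04 (adjusted p = 0.36 with an estimated correlation), with 20 of 28 members above 0 and a median change of 0.08. The protease Ctsl (0.40) and the cholesterol exporters Npc2 (0.43) and Npc1 (0.33) had the smallest p values. Cd68, a lysosomal glycoprotein of macrophages, stood at 9.66 and 10.52 on hemophagocytes 3 and 5 and between 7.21 and 7.50 on all other arrays. Adjusted over the list alone, 0 lysosome members passed, and the call ended without hemophagocyte 5, where the median fell to 0.02 (adjusted p = 0.064). Complement was higher at adjusted p = 0.0036 (adjusted p = 0.38 with an estimated correlation), with 7 of 11 members above 0. The C5a receptor C5ar1 (0.42) passed over the list alone, as the 1 member that did, and C1qc (1.11), Cfb (0.59) and properdin, Cfp (0.16), did not. The complement call ended without hemophagocyte 5 (adjusted p = 0.11) or resting macrophage 3 (adjusted p = 0.12). Chemokines and their receptors were called at adjusted p = 0.018 (adjusted p = 0.38 with an estimated correlation), with 15 of 27 members above 0 and a median change of 0.01, or -0.004 to 0.037 when single arrays were left out. Ccl5, which attracts T cells, stood at 10.43 and 10.74 on hemophagocytes 3 and 5, at 8.18 and 7.36 on hemophagocytes 6 and 2, and at 7.38 to 7.60 on resting arrays. Ccl7 had a change of 0.45, and Cxcl3 (-0.20) and the monocyte receptor Ccr2 (-0.20) had lower values. Adjusted over the list alone, 0 of these passed. The chemokine call ended without hemophagocyte 5 (adjusted p = 0.41), resting macrophage 3 (adjusted p = 0.12) or resting macrophage 5 (adjusted p = 0.066), and with quantile (adjusted p = 0.094) or cyclic loess normalization (adjusted p = 0.051).

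**Figure D3:**
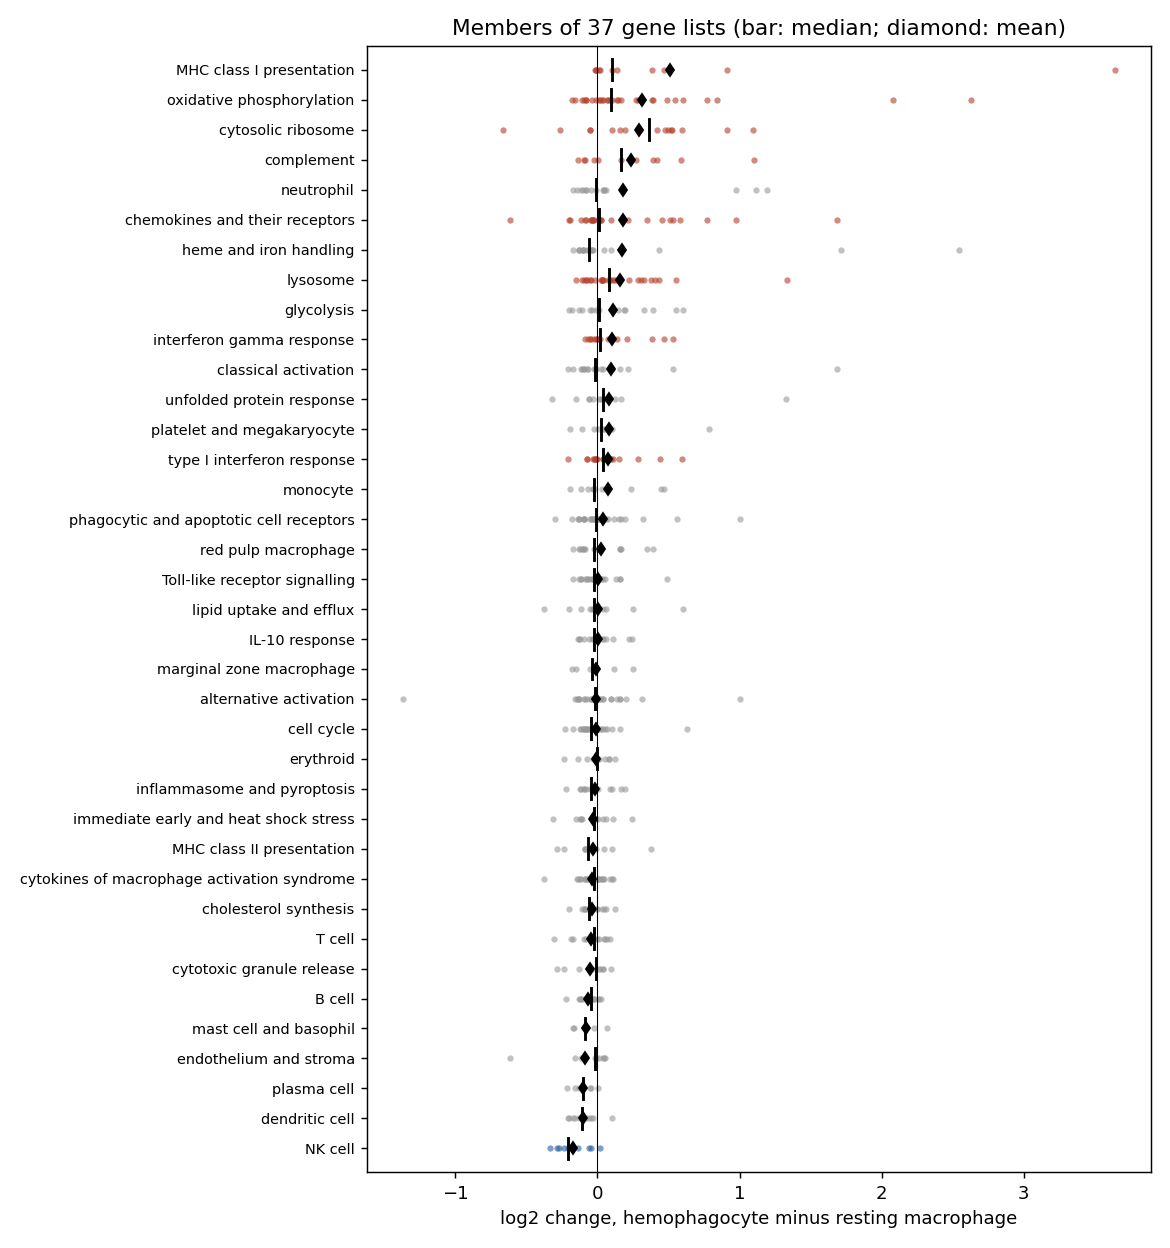
Log2 change (hemophagocyte minus resting macrophage) of each measured member of 37 gene lists, with the list's median as a bar and its mean as a diamond; red lists were higher and the blue list lower in camera at the preset correlation, and grey lists did not pass. Lists such as MHC class I presentation, with a mean of 0.51 and a median of 0.10, hold a few members with large changes.

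The lists of macrophage activation state did not pass. Alternative activation had a median change of -0.02, with 12 of 27 measured members above 0 and 0 past the threshold over all genes or over the list alone (limma camera adjusted p = 0.49). At an unadjusted p under 0.05, 0 of its members were higher and 1 was lower. This was Retnla, a secreted protein induced by IL-4, at 6.93 ± 0.23 in hemophagocytes and 8.30 ± 1.53 in resting macrophages, where resting macrophage 4 alone reached 10.48. The scavenger receptor Msr1 stood at 8.28 on hemophagocyte 5 and at 5.19 to 5.49 on the other hemophagocytes. Il4ra had a change of -0.13 and Alox15 one of 0.16. Classical activation had the same adjusted p of 0.49 and a median of -0.02, with 9 of 20 members above 0. Of all genes 36.1% lay above 0, so in neither list was the share of members above 0 lower than over all genes. Apart from Ccl5, Cxcl9, an interferon-induced chemokine, reached 8.95 on hemophagocyte 3 and 6.90 to 7.17 elsewhere, and Il12a (-0.17) had lower values, as did the costimulator Cd80 (-0.21), of which a dimmer probe set had a change of 0.07. Neither list was compared with the other.

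Heme and iron handling did not pass as a list (adjusted p = 0.49), and its median change of -0.06 was opposite in sign to its mean of 0.17. In the mixed version of fry, which takes rises and falls together against no change, its adjusted p was 0.049. That version is not among the alternatives counted below. The 2 of the list's 22 members that passed adjusted over the list alone were Ftl1 and Hp, the hemoglobin-binding haptoglobin (change 0.43), against 0 over all genes. Fth1, the ferritin heavy chain, averaged 10.02 ± 0.91 in hemophagocytes and 8.31 ± 1.09 in resting macrophages and did not pass, and Cp stood at -0.13. Phagocytic and apoptotic cell receptors did not pass (adjusted p = 0.23), with Mertk, a receptor for apoptotic cells, at 0.17, Abca7 at 0.15, Fcgr2b at -0.13 and the integrin Itgav at -0.30. In lipid uptake and efflux (adjusted p = 0.71), Apoe, the main apolipoprotein of macrophages, stood at -0.37, Fabp5 at 0.60 and Nr1h3 at 0.25. Cytokines of macrophage activation syndrome (adjusted p = 0.91) included Il18r1 at -0.38, Tnf at -0.12 and Il10ra at 0.11. The IL-10 response list (adjusted p = 0.71) included Bcl3 at 0.24 and Socs3 at -0.09 (0.01 in a dimmer probe set). In Toll-like receptor signalling (adjusted p = 0.45), Tlr13 stood at 0.49 and Traf6 at 0.16. Apart from Ftl1 and Hp, none of these members passed over their list alone.

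The remaining program lists did not pass either. Glycolysis and the unfolded protein response both had adjusted p = 0.11. Glycolysis included Ldha (0.39), Pkm (0.33) and Pgam1 (0.19), and passed at adjusted p = 0.029 without hemophagocyte 6. In the unfolded protein response the chaperone Hsp90b1 reached 9.96 on hemophagocyte 3, against 5.95 ± 0.05 in resting macrophages. Adjusted p was 0.79 for inflammasome and pyroptosis, 0.86 for cholesterol synthesis, 0.89 for cytotoxic granule release, 0.90 for MHC class II presentation, 0.91 for immediate early and heat shock stress, and 0.97 for the cell cycle. H2-Oa (-0.28) and H2-Aa (-0.23) of the class II list, Msmo1 (-0.20) of cholesterol synthesis, Unc13d (-0.23) of granule release and Rrm1 (-0.23) of the cell cycle had lower values that did not pass.

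Among cell type markers, the NK cell list was lower at adjusted p = 0.036 (adjusted p = 0.64 with an estimated correlation). Its median change was -0.21, 8 of 9 members lay below 0, and 0 passed over the list alone. Gzma (-0.29), Klrd1 (-0.27), Ncr1 (-0.23) and Klrb1c (-0.21) had the smallest p values. Their group means lay between 5.45 and 6.87, and the olfactory and vomeronasal receptor genes also had lower values. The NK call ended without hemophagocyte 3 (median change -0.13, adjusted p = 0.18), resting macrophage 3 (adjusted p = 0.060) or resting macrophage 5 (adjusted p = 0.11). Markers of the macrophages themselves did not pass, with adjusted p = 0.75 for red pulp macrophages and 0.71 for marginal zone macrophages and for monocytes. C1qa of the red pulp list had a change of 0.39 and the iron exporter Slc40a1 one of -0.17. Neutrophil markers did not pass (adjusted p = 0.27), although Lcn2, which binds bacterial siderophores, S100a8 and S100a9 had changes of 1.20, 1.12 and 0.98. These were largest on hemophagocyte 3, at 8.70, 8.02 and 9.12. Erythroid markers did not pass (adjusted p = 0.79) with 6 of 12 measured members above 0, and the red cell membrane protein Epb42 (-0.24) was lower when adjusted over the list alone. The platelet chemokine Pf4 stood at 10.35 and 9.11 on hemophagocytes 3 and 5, in a platelet list with adjusted p = 0.71. Adjusted p was 0.17 for dendritic cells, 0.49 for plasma cells and for mast cells and basophils, 0.54 for B cells, 0.91 for endothelium and stroma, and 0.98 for T cells.

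In 17 of the 28 lists that did not pass, the median, the mean and the test did not share a sign. These were alternative activation, classical activation, heme and iron handling, phagocytic receptors, lipid uptake and efflux, cytokines of macrophage activation syndrome, the IL-10 response, Toll-like receptor signalling, inflammasome, immediate early stress, the cell cycle, and the markers of neutrophils, monocytes, red pulp and marginal zone macrophages, erythroid cells and T cells. In the 9 lists that passed they did.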

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

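The tests of hemophagocytes 3 and 5 and of other cell types, and the count of genes and the share of hemophagocytes in hemophagocyte 2, were chosen after the result was seen. Single arrays stood far from the other 3 of their group in 31 of 394 groups of values examined, where chance marks about 1 in 20. Of these, 18 were on hemophagocyte arrays and 13 on resting arrays. Hemophagocyte 3 stood apart with high values for Cxcl9 (8.95) and Rpl10a (9.14) and low values for Fcrla (6.98), Cr2 (5.68), Ccr2 (5.38), Siglech (7.05), Cpa3 (5.29) and Fcer1a (5.45). Hemophagocyte 5 was high for Msr1 (8.28), Cp (5.58) and the means of the red pulp macrophage (6.76) and monocyte (6.69) lists, and low for Tyms (6.36). Hemophagocyte 2 was low for Rps20 (7.81), Fth1 (8.66), B2m (5.17) and Kit (5.90), and hemophagocyte 6 for Gata1 (6.28). Resting macrophage 3 was high for Rps20 (7.86) and Derl3 (7.09). Resting macrophage 4 was high for Timd4 (7.93) and Cmpk2 (5.91) and low for Nr4a1 (6.69). Resting macrophage 5 was high for Tex45 (6.25), Zcchc13 (6.66) and Rpl27 (7.26) and low for Cxcl9 (6.90) and Oasl1 (7.05). Resting macrophage 6 was high for Kit (6.17) and Sdc1 (6.84) and low for Lcn2 (5.79). Among 13767 probe sets with several genes or none listed, limma called 0, with 335 higher and 825 lower at an unadjusted p under 0.05.

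Of the 35 splits of the 8 arrays into groups of 4, only the real one (1 of 35) gave as many as 2 genes higher. The highest of the others gave 0. This is the smallest share that 35 splits can give, so chance is less likely for this count but is not excluded. For genes lower, all 35 gave at least 0 and the highest of the others gave 0, so the count of 0 says nothing. For lists higher, 5 of the 35 splits gave as many as the real 8, the highest of the others 10, and for lists lower 11 gave at least the real 1, the highest of the others 9, so chance cannot be excluded for either. Which side of a split with 2 hemophagocytes in each group counts as higher is arbitrary. Counted in either direction, 8 of the 35 splits gave at least 8 lists, and these 8 all kept hemophagocytes 3 and 5 on 1 side.

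The 8 higher lists were weighed against 3 technical explanations. For a wider signal range of abundant genes, the mean change of all 154 members was 0.22. Of 10000 random lists matched on mean level the highest reached 0.04, which puts the members at percentile 100. The percentile is no test, since the 8 lists were picked for higher values in these same data and the random genes were drawn singly. The matched lists themselves had a median change of -0.03, so genes of that level did not rise on average over the hemophagocyte arrays. The 99th percentile of gene values was 8.22 on hemophagocytes 3 and 5 and 8.09 to 8.14 on the other arrays. A wider range on these arrays alone was not tested, since the matched lists average all hemophagocyte arrays. The calls may come from hemophagocytes 3 and 5, since 0 of the 8 lists passed without them, 8 passed without hemophagocytes 2 and 6, and 3 to 7 without each other pair. Whether these arrays differ by RNA yield or by the state of the captured cells was not tested. Transcripts of engulfed or adjacent cells cannot be told apart from the macrophages' own: 0 of 10 marker lists of other cells passed as higher, but the upper 95% bound of the change lay below the smallest mean change of the 8 lists, 0.08, in only 6 of them, and reached 0.40 for neutrophils and 0.43 for platelets.

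The lower NK cell list could be array background. Its mean change of -0.17 lay at percentile 52.67 of 10000 lists of olfactory and vomeronasal receptor genes matched on mean level, whose own mean was -0.17. A true difference in NK transcripts was not tested apart from this and stays open.

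Hemophagocyte 2 resembled resting macrophage 3 more than any hemophagocyte array. Hemophagocyte 6 also correlated more with each of the 4 resting arrays (0.968 to 0.971) than with any hemophagocyte (at most 0.965). It stood with hemophagocytes 3 and 5 for B2m, at 9.67 to 10.34, but near the resting arrays for Cd68 (7.50) and C1qc (7.07), and whether it is mislabelled was not tested. Hemophagocyte 2 and resting macrophage 3 both had a low mean of the olfactory and vomeronasal receptor genes, at 5.95 and 5.99. Hemophagocyte 3 stood at 5.75 and the remaining arrays at 6.05 to 6.16. Whether this shared low background underlies their resemblance was not tested. A fit without hemophagocyte 2 and resting macrophage 3 gave the 20 genes of smallest p that were higher. On these, resting macrophage 3 lay at a median position of -0.02 between the group means (0 resting, 1 hemophagocyte). This met the criterion set beforehand against its being a mislabelled hemophagocyte array, a median position below 0.25. It does not settle that label, since hemophagocyte 2, if rightly labelled, shows that a hemophagocyte array can lie near 0. Hemophagocyte 2 lay at 0.06, which met the criterion set beforehand for a mislabelled resting array, a median position below 0.25. Looked at afterwards, it was nearer the hemophagocytes in 7 of the 20 genes, at 0.97 for Gng5, 0.92 for Saa3 and 0.73 for S100a6, while resting arrays left out in the same way were nearer them in 0 or 1 gene. The 7 include Rps20 at 0.59, for which resting macrophage 3 also stood at 0.60, and Ndufb8 at 0.52. The median and this later count point different ways, so whether hemophagocyte 2 is a mislabelled resting array stays open. A smaller hemophagocyte share in this pool cannot be told apart from the array's own variation: at the share that suited it best, which was 0, a pure resting profile, 5 of the 20 genes lay more than 1 log2 unit from the mixture, but so did 4 to 6 on the other hemophagocyte arrays treated in the same way (best shares 0.66, 0.63 and 0.07 for hemophagocytes 3, 5 and 6), and 1 or 2 on the resting arrays. A loss of transcripts in amplification was not tested.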

How the results depend on the processing

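The covariate for array background, the pairs of arrays left out and the exact permutation of array means were chosen after the data were seen. The count of 2 genes higher became 1 with median centring, with cyclic loess, with the intensity trend and robust prior, and with the background covariate, 5 without hemophagocyte 2 and resting macrophage 3, and 1 to 11 when single arrays were left out; 0 genes were lower in every setting. With the replicate block it was 7, without S100a6 (adjusted p 0.21). Hemophagocyte 2 and resting macrophage 4 have no partner of their number, so they add nothing to that contrast. The values do not settle whether a shared number marks a shared day or batch. The deviations of arrays numbered 3, 5 and 6 correlated at 0.17, 0.07 and 0.12, all above 0. Arrays of different numbers ran from -0.24 to 0.18, and not every array correlated best with its own number. Gng5 passed in 19 of 19 alternatives (log2 change 1.51 to 1.72, adjusted p 5.1e-05 to 0.040) and S100a6 in 6 (1.87 to 2.18, adjusted p 0.019 to 0.66). The 8 higher lists became 0 with an estimated correlation, with fry (smallest adjusted p 0.53), which tests members against no change and not against other genes, and without hemophagocytes 3 and 5, and 4 to 9 when single arrays were left out. They were 7 with quantile normalization and with cyclic loess, which ended the chemokine call, and 6 with the background covariate, which ended the ribosome (median change 0.02, adjusted p 0.92) and interferon gamma (adjusted p 0.37) calls. The ribosome median was -0.15 without hemophagocytes 3 and 5. Exact permutation gave 0 lists in either direction after adjustment. That count says nothing about them, since 22 of the 37 would have to reach its smallest p for any to pass. The unadjusted permutation p was 0.4 for the ribosome, 0.343 for chemokines, 0.229 for type I interferon, and 0.114 for the lysosome and complement. It was 0.0571 for MHC class I presentation and interferon gamma. Of the 8 higher lists, only oxidative phosphorylation reached the smallest p. The NK list reached it too, and so did heme and iron handling, which had not passed in camera. Oxidative phosphorylation and MHC class I presentation each passed in 18 of 22 alternatives, permutation included, the lysosome in 17, and chemokines in 13. The 1 lower list became 0 with quantile normalization, array weights, the background covariate (median change -0.03, adjusted p 0.95), an estimated correlation, fry, without hemophagocytes 3 and 5, without hemophagocyte 2 and resting macrophage 3, and in 3 of the single-array settings. With the filter on genes below the median level, where the count was also 0, the NK list kept 3 members and was not tested; in all, 5 lists had too few members left. No result reversed. Of 28 lists that did not pass, 2 passed somewhere (glycolysis without hemophagocyte 6, heme and iron handling with that filter) and 22 changed direction without passing. Of the named genes, 5 that had not passed did so somewhere, and 19 changed sign without passing. Why calls ended was not tested, except that leaving arrays out also leaves fewer samples. Dim genes lie in the array background, which limits what a change in them can show.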

Other observations

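A group of abundant transcripts was high on hemophagocytes 3, 5 and 6 and near resting level on hemophagocyte 2. These genes lie outside the naming rule and were chosen after their values were seen. The interferon-induced membrane protein Ifitm3 stood at 10.37, 10.65 and 11.46 on hemophagocytes 3, 5 and 6, at 6.65 on hemophagocyte 2 and at 6.64 to 7.33 on resting macrophages. Tmsb4x, which binds actin monomers, stood at 10.64, 10.52 and 10.85, at 7.77 on hemophagocyte 2, and at 7.38 to 8.69 on resting macrophages. The antioxidant enzymes Gpx1 and Txn1 followed, with Gpx1 at 8.89, 8.45 and 9.91 against 6.45 on hemophagocyte 2 and Txn1 at 10.39, 9.55 and 10.02 against 7.48. So did cytochrome c, Cycs, at 7.72, 7.01 and 8.29 against 5.84. Arf6, a small GTPase of membrane traffic, and Rps10 completed the genes called without hemophagocyte 2, with limma adjusted p of 0.044 and 0.014 in that setting. Rps10 stood at 7.094 on hemophagocyte 2, above the resting arrays at 6.816 to 7.003. With all arrays, limma adjusted p was 0.75 for each of these 7 genes. Ifitm3, Tmsb4x, Gpx1 and Txn1 also passed with the replicate number as a block. Hemophagocyte 2 adds nothing to that contrast, since no resting array shares its number, so this gives no separate support. Leaving out pairs of hemophagocytes, a choice also made after seeing the data, gave 57 genes higher without 2 and 6, 13 without 2 and 3 and without 2 and 5, 5 without 3 and 6, 4 without 5 and 6, and 2 without 3 and 5.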
